A study of Mus musculus with 9 samples.

How the data were processed

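RNA was sequenced from 9 samples of mouse macrophages in 3 groups of 3. Macrophages of the synovial lining (samples A, B and C) and of the interstitial synovium (samples D, E and F) were sorted from hind paws of healthy Cx3cr1-GFP mice, which carry green fluorescent protein (GFP) under control of the gene for the fractalkine receptor. Both sorts took CD45+CD11b+F4/80+ cells, with GFP present for the lining and absent for the interstitial group. Bone marrow-derived macrophages (BMDM, samples G, H and I) were grown from marrow of C57BL/6 mice for 5 days in medium conditioned with macrophage colony-stimulating factor (MCSF). Per the labels, RNA was purified on RNeasy columns, and 500 ng went into stranded, poly(A)-selected TruSeq libraries that were read on a HiSeq instrument as single 101 bp reads. A poly(A) library counts reads and carries no molecular identifiers, so intervals and floors given here cover counting error only. Nothing in the labels says whether the samples of a group are separate animals, pools or aliquots, so every p-value measures the spread between these samples.

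The authors deposited a single table of read counts per gene, with no normalisation. Per the file headers, featureCounts 1.6.1 assigned reads to exons, summed them over Ensembl genes (GRCm38, release 91) and counted reverse-stranded reads, with no option for multi-mapping reads or for reads that overlap several genes, so reads of near-identical gene copies are lost or assigned unevenly. The submitters' processing notes also name bcl2fastq 2.17.1.14, cutadapt 1.15, STAR 2.5.4a, R 3.5.0 and DESeq2 1.20.0, with no settings. The stranded counting matches a stranded kit. The table holds 53465 genes, of which 53274 were matched to a symbol and 191 were not. Those without a symbol were tested under their identifier. Coordinates are the outermost exon ends in the table itself (GRCm38), and gene types came from a GENCODE annotation of the same build. Values for Cd209, Clec4a, Hspa1 and Hba family members, whose copies resemble each other closely, carry this counting limit.

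Total counts per library ranged from 2194920 to 22499823. In the sorted groups a floor of 3 counts corresponds to between 0.269 and 1.37 CPM (counts scaled to a common library total, the usual CPM unit) in a library, and over a whole group to 0.187 CPM in lining, 0.169 in interstitial and 0.0477 in BMDM. Where a group had no count of a gene, the fold against that group was computed from plain library totals against 3 counts over the group's summed library and is given as "at least". Where it had 1 to 3 counts, the ratio of summed CPM is given with its exact binomial (Clopper-Pearson) 95% counting interval. Other folds come from the fitted model. CPM values are scaled by the TMM factors described next. Marker levels and the Xist ratio in the closing section were first computed as plain CPM and were changed to this scaling, so that every level is in 1 unit, after the first values had been seen. No outcome changed with it.

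Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12610. Libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood model with a mean per group was fitted to all 9 samples (robust, 6 residual degrees of freedom) and 3 contrasts were tested, 2-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, and "rose", "fell", "higher" and "lower" are used of called genes. Standard errors (SE) are the log2 fold change over the square root of its F statistic. SD is between the 3 libraries of a group. Nothing in the labels pairs a lining with an interstitial sample, so the model has no blocking term.

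Before the data were examined, 36 gene lists were fixed, of which 20 describe biology, 1 holds sort and identity markers, 13 hold markers of other cells and 2 are technical. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 32 lists with at least 5 tested members. Camera asks whether a list's genes differ from the other genes. Beside it stand the number of members called over all genes, the number adjusted over the list alone, camera with an estimated correlation, and fry, which asks whether a list's genes move, on balance, in a single direction and compares them with no other genes. In each comparison the 6 libraries were also split into 3 and 3 in all 10 ways. At the preset correlation 4, 6 and 4 of the 10 splits, the real one included, had as many list calls as the real 9, 16 and 17. The number of list calls at that setting therefore does not set the real groups apart. The tight junction, polarity, TREM2, complement, uptake and class II lists were written with some knowledge of what the published study discusses, so their counts are not independent evidence of direction. The rule for named genes was also fixed. It takes the 10 genes higher and the 10 lower with the largest fold change among those called, with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups, leaving out predicted genes, pseudogenes, receptor segments and markers of other cells. It adds up to 4 members per list with the smallest adjusted p, the 4 genes of the sort (Cx3cr1, Ptprc, Itgam and Adgre1) and 6 genes per group that exceeded both other groups. Genes and gene families outside the rule are said to have been chosen after their values were seen. Of the genes it names, 5 are not reported here, and the counts of named genes include them.

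The pipeline was tested on simulated data with the means, spread and depths of these libraries. Of genes changed 2-fold, 32% were recovered between lining and interstitial, 26% between lining and BMDM and 23% between interstitial and BMDM. For 4-fold changes these shares were 72%, 61% and 64%. False calls made up 3.70%, 4.40% and 3.33% of calls. With nothing changed, edgeR called 0 genes and camera 0 lists in each of the 3 contrasts. The simulated genes varied independently, each with the same spread in every group. The result therefore does not cover list calls that come from correlation between genes. Nor does it cover a spread that differs between BMDM and sorted libraries.

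Alternatives fixed beforehand were DESeq2 size factors, library size only, no filter, a filter at a mean of 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, a fit without robust estimation, an adjusted p under 0.01, a test against a 2-fold change (glmTreat), removal of the other-cell genes, fits of only the 6 samples compared, leaving out each sample in turn, and the other list tests. Added after the data were seen were thinning of all libraries to the smallest total, 1 surrogate variable (sva 3.50.0), a term for the lining and interstitial libraries that deviate alike, and a fit without lining C and interstitial F, both of which hold high Arg1. The term takes lining A and interstitial D as its base and is absent from BMDM. With it, comparisons with BMDM are set at the level of that base and not at the group means. All per-sample columns of the table were used.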

Results

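Transcript levels were measured by poly(A) RNA sequencing in macrophages of the mouse joint and in macrophages grown from bone marrow, with 3 samples in each of 3 groups. Lining macrophages (A, B and C) sit as a layer at the surface of the synovium, the membrane that encloses the joint cavity, and were sorted as GFP-positive cells. Interstitial macrophages (D, E and F) lie in the tissue beneath and were sorted as GFP-negative cells, and each sort was from hind paws. BMDM (G, H and I) are a standard culture model of macrophages. The libraries held 2194920, 11137451 and 2700843 counts in lining A to C and 2238261, 10807462 and 4693755 in interstitial D to F. BMDM G to I held 22499823, 19427273 and 20975304. Correlations of log2 CPM between libraries, taken across genes, which are not independent replicates, were 0.872 to 0.924 within lining, 0.850 to 0.924 within interstitial and 0.996 to 0.997 within BMDM. Between lining and interstitial libraries they ranged from 0.817 to 0.936. The highest was that of lining B with interstitial E, the deepest sorted libraries, which also had the highest chi-square per gene of these pairs (82.6, others from 28.7). Both measures grow with depth, so likeness beyond depth cannot be read from either. The first principal component, with 54.1% of the variance, parted BMDM from the sorted cells. On the second, with 16.0%, lining A to C lay at 46.0, 23.3 and 75.3 and interstitial D to F at -118, -14.1 and 1.10. It thus set every lining library above every interstitial library, with interstitial D far apart.

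**Figure D1:**
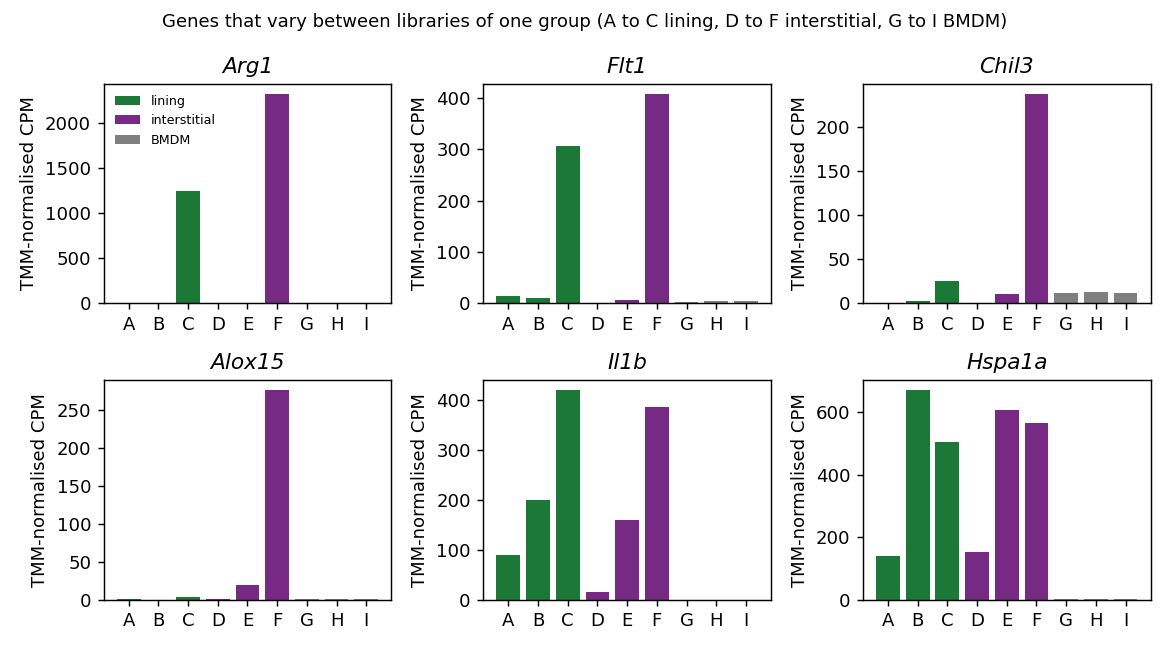
TMM-scaled CPM of 6 genes, chosen after their values were seen, in lining (A to C, green), interstitial (D to F, purple) and BMDM (G to I, grey) libraries. Arg1 and Flt1 were high in lining C and interstitial F, and Chil3 and Alox15 in interstitial F.

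The first comparison asked how the macrophages that form the lining differ from those of the interstitial synovium. Cx3cr1, the fractalkine receptor gene whose reporter defined the sort (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879, minus strand), was 138-fold higher in lining (log2 fold change 7.11 ± 0.29 SE, 707 ± 58.9 against 4.92 ± 2.66 CPM, mean ± SD, n = 3 per group, edgeR adjusted p = 1.46e-07). Among genes that did not define the sort, Olfml3, a secreted olfactomedin-like protein (ENSMUSG00000027848, chromosome 3, 103722222 to 103738001, minus strand), was 27.3-fold higher (4.77 ± 0.33, 736 ± 226 against 25.9 ± 11.4 CPM, adjusted p = 1.29e-05). Itgb5, the integrin beta 5 chain (ENSMUSG00000022817, chromosome 16, 33829665 to 33949153, plus strand), was 12.4-fold higher (3.63 ± 0.18, 783 ± 167 against 63.0 ± 8.77 CPM, adjusted p = 1.04e-06). Cd163, the haemoglobin scavenger receptor (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527, plus strand), was 5.11-fold lower in lining (-2.35 ± 0.23, 416 ± 125 against 2131 ± 502 CPM, adjusted p = 1.08e-04). Ednrb, the endothelin B receptor (ENSMUSG00000022122, chromosome 14, 103814625 to 103844402, minus strand), was 11.4-fold lower (-3.51 ± 0.43, 38.4 ± 16.9 against 441 ± 202 CPM, adjusted p = 0.00170). Lining and interstitial libraries did not overlap for any of these 5 genes. Of the other sort markers, Ptprc (CD45), Itgam (CD11b) and Adgre1 (F4/80) had log2 fold changes of -0.03 ± 0.16, 0.19 ± 0.13 and 0.53 ± 0.15 and did not pass (adjusted p = 0.949, 0.490 and 0.0636). Of 10 sort and identity genes 3 were higher, Cx3cr1, Cd68 (0.82 ± 0.15) and Fcgr1 (1.04 ± 0.24), and 5 when adjusted over the list alone (camera adjusted p = 4.26e-09, adjusted p = 0.111 with an estimated correlation). Since Cx3cr1 defined the sort, this list call follows in part from the sort, and the list was not tested without it. The call of Fcgr1, a high-affinity receptor for immunoglobulin G, was lost without lining A, B or C or BMDM I (highest adjusted p = 0.108).

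The genes with the largest differences included several with few or no counts in the other group. Myh15, a myosin heavy chain (ENSMUSG00000092009, chromosome 16, 49057486 to 49199104, plus strand), had 177 counts in lining and 0 in interstitial and was at least 65.3-fold higher, or at least 25.5-fold without interstitial E. Lbx1, a homeobox transcription factor (ENSMUSG00000025216, chromosome 19, 45232684 to 45235812, minus strand), had 206 counts in interstitial and 0 in lining and was at least 62.1-fold lower, or at least 19.0-fold without lining B. Chst1, a sulfotransferase that modifies keratan sulfate (ENSMUSG00000027221, chromosome 2, 92599707 to 92615250, plus strand), was higher by 6.86 ± 0.49 on the log2 scale (196 ± 34.6 against 1.57 ± 1.85 CPM) and by 7.76 without interstitial F. Adamtsl2, a secreted protein of the extracellular matrix, was higher by 5.25 ± 0.49 (38.7 ± 13.3 against 0.982 ± 0.0889 CPM). Among genes lower in lining, the chemokine gene Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799, plus strand) differed by -6.49 ± 1.04 on the log2 scale (0.847 ± 0.950 against 75.6 ± 82.5 CPM, and -5.09 without interstitial D). Barx2, a homeobox gene, differed by -5.65 ± 0.79 (0.286 ± 0.495 against 25.7 ± 15.4 CPM, and at least 36.8-fold lower without lining B, where its few lining counts lay). The lectin genes Cd209f, Cd209g and Cd209b had values of -6.20 ± 1.06, -5.68 ± 1.19 and -5.54 ± 1.26. Each lost its call in several leave-one-out fits, Cd209f without lining A or any BMDM library (highest adjusted p = 0.0980), Cd209g without any of A, B, C, G, H or I (0.123) and Cd209b without any of A, B, G, H or I (0.134). Without interstitial D their values were -5.25, -4.36 and -3.97, and Cd209f had 2 lining counts left without lining B (299-fold lower, counting interval 82.7 to 2470), Cd209g was -6.72 without lining A and Cd209b -7.22 without lining C.

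Genes of cell junctions and of cell polarity were measured because the lining forms a layer. The gene for junctional adhesion molecule A, F11r, a component of tight junctions (ENSMUSG00000038235, chromosome 1, 171437535 to 171464603, plus strand), was 5.38-fold higher in lining (2.43 ± 0.21, 372 ± 74.5 against 68.3 ± 17.6 CPM, adjusted p = 3.74e-05). Of 12 tested tight junction genes 2 passed, over all genes and adjusted over the list alone, both higher. The other was Cgnl1 (1.12 ± 0.30), whose call was lost in each leave-one-out fit except without interstitial D (highest adjusted p = 0.133). Tjp1, which encodes ZO-1, had 8.75 ± 7.38 against 1.39 ± 1.63 CPM and did not pass (adjusted p = 0.193). The tight junction list was not called (adjusted p = 0.159). In the planar cell polarity and apicobasal polarity list 2 of 18 genes passed, also 2 over the list alone, both higher. The protocadherin gene Fat3 (ENSMUSG00000074505, chromosome 9, 15910189 to 16501285, minus strand) had 334 against 2 counts, a ratio of 185-fold with a counting interval of 50.8 to 1530 (fitted log2 fold change 7.26; 72.2-fold, 19.8 to 599, without interstitial E and at least 90.6-fold without interstitial F). The core polarity gene Vangl2 (ENSMUSG00000026556, chromosome 1, 172000960 to 172028444, minus strand) was higher by 4.17 ± 0.80 (7.93 ± 2.81 against 0.363 ± 0.328 CPM, adjusted p = 0.00973). That list was called higher (adjusted p = 0.0284, adjusted p = 0.168 with an estimated correlation), a call lost without lining B or C or interstitial E or F (adjusted p = 0.0506, 0.0530, 0.103 and 0.124). The call of planar cell polarity and apicobasal polarity was also lost with no filter, a filter on mean CPM, only the 6 sorted libraries, the term for the matched libraries and neither lining C nor interstitial F (0.0874, 0.0543, 0.0508, 0.0535 and 0.238). Among 12 adherens junction and desmosome genes 1 passed, Jup, the plakoglobin gene, which was lower (-1.12 ± 0.18, 74.3 ± 10.7 against 161 ± 28.5 CPM), and 2 passed, both lower, over the list alone (list adjusted p = 0.311). The junction and polarity lists were written with knowledge of the study, so they are not independent evidence of direction.

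Uptake, lipid-handling and lysosome genes differed in both directions, more often higher in lining. Of 20 receptors and bridging molecules for apoptotic cell uptake 6 were higher and 4 lower (8 and 4 adjusted over the list alone). Beside Itgb5 the higher members included Itgav, its integrin partner (1.72 ± 0.20), and Elmo1, an adaptor for engulfment (1.13 ± 0.18). The lower members included Cd163 and the mannose receptor Mrc1 (-1.18 ± 0.25, call lost without lining A or B, highest adjusted p = 0.0926). The list of apoptotic cell uptake receptors and bridging molecules was called higher (adjusted p = 0.0164, adjusted p = 0.168 with an estimated correlation), a call lost without interstitial F (adjusted p = 0.154), with no filter (0.102) and without lining C and interstitial F together (0.151). Of 24 TREM2 and lipid-handling genes 7 were higher and 1 lower (10 and 2 over the list alone, camera adjusted p = 4.26e-06, adjusted p = 0.111 with an estimated correlation). Trem2, a lipid-sensing receptor (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, plus strand), was 3.10-fold higher (1.63 ± 0.15, 771 ± 138 against 249 ± 26.9 CPM), and the receptor kinase gene Axl was higher by 2.52 ± 0.47 (285 ± 141 against 48.7 ± 30.7 CPM, call lost without interstitial E or BMDM G or I, highest adjusted p = 0.0568). The lower member was Fabp4 (-3.10 ± 0.66), a fatty acid-binding protein gene that also marks adipocytes and endothelium, whose call was lost without lining A (0.0761) and which had 3 lining counts left without lining B (28.3-fold lower, counting interval 9.61 to 138). Among 26 lysosome genes 9 were higher and 2 lower (14 and 2 over the list alone, camera adjusted p = 5.05e-07, adjusted p = 0.196 with an estimated correlation). Ctsd, the cathepsin D gene (ENSMUSG00000007891, chromosome 7, 142375911 to 142388038, minus strand), was 9.58-fold higher (3.26 ± 0.20, 4508 ± 938 against 471 ± 84.0 CPM, adjusted p = 2.80e-06). The cathepsin K gene Ctsk was lower (-1.15 ± 0.24, call lost without lining A or B or interstitial E, highest adjusted p = 0.0756). The uptake and TREM2 lists were also written with knowledge of the study.

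Genes often used to describe resident macrophages went both ways, while those of alternative activation were more often lower. Of 25 resident tissue macrophage genes 4 were higher and 7 lower in lining (6 and 10 over the list alone, list adjusted p = 0.963). Vsig4, a receptor for complement C3 fragments (ENSMUSG00000044206, chromosome X, 96247203 to 96293438, minus strand), was 10.9-fold higher (3.45 ± 0.33, 1969 ± 476 against 181 ± 84.8 CPM, adjusted p = 1.69e-04), while Cd163 and Mrc1 were lower. The alternative activation list was called lower (adjusted p = 1.65e-04, adjusted p = 0.196 with an estimated correlation), with 4 of 19 genes lower and 1 higher (6 lower and 2 higher over the list alone). Its lower members were Cd163, Mrc1, the chemokine gene Ccl24 (-2.28 ± 0.28, 50.9 ± 11.4 against 248 ± 97.6 CPM) and the lectin gene Clec10a (-4.20 ± 0.49, 22.4 ± 8.51 against 427 ± 278 CPM, and -3.55 without interstitial D). The median of the list, -2.35, stands beside a median of -1.86 for dendritic cell markers and -1.73 for endothelial markers (adjusted p = 0.00245 and 8.45e-04, and 0.111 for each with an estimated correlation), and both sorts took cells with CD45, CD11b and F4/80. Of 18 complement genes 2 were higher, Vsig4 and C3ar1 (0.59 ± 0.14, call kept only without interstitial E, highest adjusted p = 0.0768), and 1 lower, properdin (Cfp, -2.03 ± 0.25), with 3 and 4 over the list alone (list adjusted p = 0.972). For MHC class II antigen presentation 2 of 16 were higher, Cd40 (1.21 ± 0.19) and Ctss (0.74 ± 0.13), and 1 lower, Cd86 (-0.84 ± 0.21, call kept only without interstitial F, highest adjusted p = 0.129), with the same counts over the list alone (list adjusted p = 0.576). The complement and class II lists were likewise written with knowledge of the study.

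Chemokine, receptor and growth factor genes split between the groups. Of 22 inflammatory cytokine and chemokine genes 3 were higher and 3 lower (3 and 5 over the list alone, list adjusted p = 0.621). Ccl4 (1.94 ± 0.21) and Cxcl16 (1.12 ± 0.12) were higher, and Ccl6 (-2.14 ± 0.17, 137 ± 12.7 against 605 ± 119 CPM) and Ccl9 (-1.43 ± 0.16) lower. Of 23 pattern recognition receptors 3 were higher and 4 lower (3 and 6 over the list alone, list adjusted p = 0.648), among them Tlr2 (1.66 ± 0.22), which senses bacterial lipoproteins, and Clec12a (1.19 ± 0.19) higher, and Clec4a1 (-1.93 ± 0.25) and Clec4a2 (-1.33 ± 0.18) lower. The growth factors and their receptors were called higher as a list (adjusted p = 0.0408, adjusted p = 0.168 with an estimated correlation), with 3 of 22 higher and Ednrb lower (6 and 4 over the list alone). The higher members were Fgf2 (4.55 ± 0.44, 52.5 ± 10.2 against 2.09 ± 1.26 CPM), Tgfbr1 (1.46 ± 0.18) and Pdgfb (2.82-fold). Of the leave-one-out fits, those without interstitial E or BMDM I kept this call of growth factors and their receptors, and those without A, B, C, D, F, G or H did not (adjusted p = 0.0514, 0.0983, 0.170, 0.201, 0.0836, 0.0574 and 0.0529). It was also lost with no filter, a filter on mean CPM and neither lining C nor interstitial F (0.0874, 0.0541 and 0.238). Of 30 macrophage transcription factors 4 were higher and 1 lower (5 and 1 over the list alone, list adjusted p = 0.311), including Irf8 (0.90 ± 0.13) and Cebpa (1.01 ± 0.16). Anti-inflammatory mediators had 2 higher and 2 lower of 18 (4 and 2 over the list alone, list adjusted p = 0.963), with the interleukin 10 receptor gene Il10ra higher (0.75 ± 0.13) and haem oxygenase 1 (Hmox1, -0.81 ± 0.13) lower. Monocyte genes had Vcan, the proteoglycan versican, higher (4.32 ± 0.36, 321 ± 56.2 against 14.9 ± 8.44 CPM) and F13a1, a coagulation factor chain, lower (-2.10 ± 0.34) among 18 (2 and 1 over the list alone, list adjusted p = 0.648).

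Few or no genes passed in several fixed lists. In the type I interferon list edgeR called 0 of 25 genes over all genes and over the list alone, with 1 gene higher and 2 lower at an unadjusted p under 0.05, DESeq2 calling 1 higher and 2 lower and limma-voom 1 higher. In the cell cycle list it called 0 of 30, with 2 higher at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. The dissociation and immediate early list had 0 of 24 called, with 2 higher and 2 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. The adjusted p of these lists was 0.621, 0.496 and 0.963. Cholesterol synthesis had 1 gene higher of 22 (Dhcr7, 0.96 ± 0.23, call lost in 7 of 9 leave-one-out fits, those without A, B, D, E, G, H or I, highest adjusted p = 0.127) and glycolysis 1 lower of 20 (Hk3, -0.73 ± 0.16, call lost without lining A or C, highest 0.0664). Both counts were the same over the list alone (list adjusted p = 0.148 and 0.675).

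Markers of other cells were measured beside these groups. Neutrophil markers had the median -2.68 in lining against interstitial, with 0 of 9 called (camera adjusted p = 0.114). Mast cell and eosinophil markers had the median -1.19, with 1 of 10 lower (camera adjusted p = 0.237). Dendritic cell markers were called lower in lining as a list, with 1 of 10 lower and 4 over the list alone (adjusted p = 0.00245, adjusted p = 0.111 with an estimated correlation). Endothelial markers were also called lower, with 1 of 11 lower and 3 over the list alone (adjusted p = 8.45e-04, adjusted p = 0.111). Their single called members, Cd209a (-2.49 ± 0.62, 11.6 ± 10.4 against 66.2 ± 43.3 CPM) and Pecam1 (-2.55 ± 0.66, 2.69 ± 1.76 against 17.3 ± 14.0 CPM), were called in 2 of the 9 leave-one-out fits each. Cd209a was called without lining C (-3.22) or interstitial F, with a highest adjusted p of 0.132 and a value of -1.87 without interstitial D. Pecam1 was called without interstitial D or E, with a highest adjusted p of 0.169 and values of -3.23 without lining B and -1.69 without interstitial F. S100b, fixed as a Schwann cell marker, was higher in lining by 7.75 ± 0.65 (282 ± 98.2 against 0.787 ± 1.36 CPM, and at least 573-fold without interstitial E, the interstitial library in which it was counted). Fibroblast markers had 1 of 20 higher, Pdpn (1.92 ± 0.48, call kept only without interstitial D or F, 2.88 without interstitial F, highest adjusted p = 0.112), and over the list alone 1 higher and 3 lower (list adjusted p = 0.216). Osteoclast markers had Tnfrsf11a (0.85 ± 0.22, call kept only without interstitial E, highest adjusted p = 0.149) higher and Ctsk and Atp6v0d2 (-2.21 ± 0.50, call lost without lining B or interstitial F, highest 0.0842) lower of 10. Over the list alone 1 was higher and 4 lower (list adjusted p = 0.216). Among 7 pericyte and smooth muscle markers Cspg4 was higher (2.37 ± 0.55, 851 ± 158 against 164 ± 109 CPM, call kept only without interstitial D or F, highest adjusted p = 0.114; list adjusted p = 0.818).

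In total edgeR called 473 genes higher and 259 lower in lining of 12610 tested, of which 271 and 169 differed at least 2-fold. With a term for the matched libraries, chosen after the data were seen, they were 744 and 539. With only the 6 sorted libraries, whose spread then excludes BMDM, they were 255 and 111, and 25 of the named genes lost their call. The term was matched on these same libraries, so the larger numbers with it are no added support. At an unadjusted p under 0.05 there were 2435 genes, against 630.5 that chance gives, and the libraries of the groups did not overlap for 18.6% of genes, against 10% by chance. Without lining A the counts were 276 and 120, without lining B 287 higher, without BMDM I 308 and 153, and without interstitial E, BMDM G or BMDM H 149, 141 and 146 lower. With library size only in place of TMM factors the share of called genes that were higher was 54.0%, against 64.6%.

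**Figure D2:**
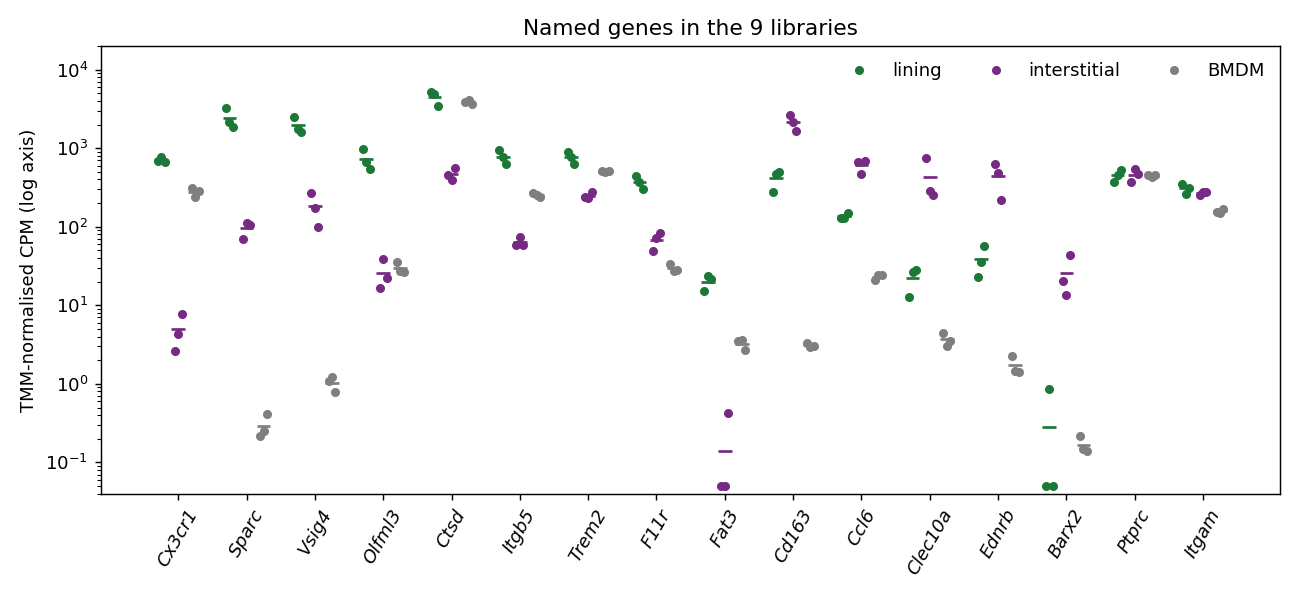
TMM-scaled CPM (log axis) of 16 named genes in the 3 lining (green), 3 interstitial (purple) and 3 BMDM (grey) libraries, with points for libraries, short lines for group means and values under 0.05 drawn at 0.05. Cx3cr1 averaged 707 CPM in lining, 4.92 in interstitial and 278 in BMDM, while Cd163 averaged 416, 2131 and 3.08.

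The second comparison asked how lining macrophages differ from macrophages grown in culture. Lyve1, a hyaluronan receptor gene (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239, minus strand), had 2045 ± 214 against 0.0885 ± 0.113 CPM in lining against BMDM (log2 fold change 14.27 ± 0.45 SE, n = 3 per group, edgeR adjusted p = 1.37e-09; 13.68 without BMDM I, and without BMDM G 1 BMDM count and a ratio of 76200-fold with a counting interval of 13700 to 3010000). Sparc, a matricellular glycoprotein (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183, minus strand), was higher by 12.96 ± 0.39 (2419 ± 717 against 0.293 ± 0.107 CPM, adjusted p = 1.08e-09). Gpr34, a receptor for lysophosphatidylserine, was higher by 11.91 ± 0.65 (399 ± 59.0 against 0.0916 ± 0.0423 CPM). Tcim (ENSMUSG00000056313, chromosome 8, 24437180 to 24438984, minus strand) had 1957 counts in lining and 0 in BMDM, at least 2560-fold higher, or at least 1640-fold without BMDM G. Olr1, the receptor for oxidised low-density lipoprotein, was at least 1920-fold higher, or at least 1230-fold without BMDM G. Slco4a1, an organic anion transporter gene (ENSMUSG00000038963, chromosome 2, 180456245 to 180474867, plus strand), was lower in lining (log2 fold change -10.20 ± 0.52, 1.05 ± 0.923 against 687 ± 104 CPM; -11.06 without lining A and -8.89 without lining B). Spp1, the osteopontin gene, was lower (-6.34 ± 0.57, 179 ± 26.6 against 14459 ± 4129 CPM). Fcrl1, a gene of the Fc receptor-like family, had 0 counts in lining and was at least 98.6-fold lower, or at least 30.1-fold without lining B.

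Resident macrophage genes were higher in lining and proliferation genes lower. Of 25 resident tissue macrophage genes 22 were higher and 1 lower (23 and 1 adjusted over the list alone, camera adjusted p = 1.11e-25, adjusted p = 0.0584 with an estimated correlation). Cd163 was higher by 7.07 ± 0.30 and the efferocytosis receptor gene Mertk by 3.31 ± 0.18. All 30 cell cycle genes were lower, over all genes and over the list alone (adjusted p = 3.44e-23, adjusted p = 0.0584 with an estimated correlation), among them Mcm5, a helicase subunit (-3.40 ± 0.19, 24.6 ± 3.99 against 263 ± 12.7 CPM), and Bub1b, a mitotic checkpoint kinase (-3.71 ± 0.21). Type I interferon genes were lower for 19 of 25 (21 over the list alone, adjusted p = 1.14e-07, adjusted p = 0.147 with an estimated correlation), such as Oas1a (-2.39 ± 0.28) and Irf7 (-2.27 ± 0.29). Cholesterol synthesis genes were lower for 11 of 22 (13 over the list alone, adjusted p = 4.19e-04, adjusted p = 0.171 with an estimated correlation), such as Lss (-2.41 ± 0.29) and Cyp51 (-1.50 ± 0.23).

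Uptake, complement, antigen presentation and signalling lists were called higher in lining by camera at the preset correlation. At that setting 6 of 10 splits of these libraries, the real one included, had as many list calls as the real 16. Uptake genes had 13 higher and 2 lower of 20, with the same counts over the list alone (adjusted p = 1.71e-06, adjusted p = 0.0299 with an estimated correlation). Complement genes had 11 higher and 3 lower of 18 (11 and 4 over the list alone, adjusted p = 2.96e-05 and 0.0804, the second with an estimated correlation, as in the pairs that follow), among them C1qa (4.28 ± 0.29, 4029 ± 1165 against 208 ± 6.90 CPM). Class II presentation had 15 of 16 higher (15 and 1 over the list alone, 2.96e-05 and 0.147), among them Cd40 (3.76 ± 0.21) and Cd86 (3.84 ± 0.24). Alternative activation genes had 11 of 19 higher, also 11 over the list alone (5.71e-08 and 0.110). Growth factors and their receptors had 12 higher and 2 lower of 22 (13 and 2 over the list alone, 5.26e-06 and 0.0444), such as Pdgfc (6.76 ± 0.28). Macrophage transcription factors had 19 higher and 5 lower of 30 (19 and 5 over the list alone, 2.74e-05 and 0.0998), including Klf4 (4.59 ± 0.15, 745 ± 61.9 against 30.9 ± 2.05 CPM) and Cebpa (3.36 ± 0.17). Anti-inflammatory mediators had 11 higher and 3 lower of 18, the same over the list alone (4.49e-07 and 0.0299), including Il10ra (2.45 ± 0.14). Inflammatory cytokines and chemokines had 12 higher and 2 lower of 22, the same over the list alone (0.00454 and 0.326), including Cxcl16 (1.59 ± 0.12). Pattern recognition receptors had 13 higher and 2 lower of 23, the same over the list alone (0.0166 and 0.459, and the call of pattern recognition receptors was lost at 0.0750 with the term for the matched libraries), including Tlr2 (3.19 ± 0.23). That term sets the comparison at the level of lining A. The uptake, complement and class II lists were written with knowledge of the study.

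TREM2 and lipid-handling genes went both ways, with 5 higher and 10 lower of 24, the same over the list alone, and no call of the list (adjusted p = 0.359). The cholesterol exporter gene Abca1 was higher (5.55 ± 0.24, 897 ± 99.7 against 19.1 ± 2.45 CPM), as was Apoe (4.68 ± 0.33), while the lysosomal lipase gene Lipa was lower (-1.87 ± 0.15). Lysosome genes had 10 higher and 5 lower of 26 (10 and 6 over the list alone, list adjusted p = 0.256). The following lists had the same counts over the list alone. Tight junction genes had 5 higher and 2 lower of 12 (0.327), and polarity genes 8 and 2 of 18 (0.0841). Adherens junction genes had 4 and 1 of 12 (0.414), monocyte genes 7 and 2 of 18 (0.152) and glycolysis genes 1 and 5 of 20 (0.0570). None of these lists was called. F11r was higher by 3.63 ± 0.22 and Cgnl1 lower (-2.76 ± 0.28).

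Markers of handling, other cells and sex differed in the same comparison. Immediate early and heat shock genes had 20 higher and 1 lower of 24 (20 and 2 over the list alone, adjusted p = 1.11e-25, adjusted p = 0.0998 with an estimated correlation), such as Fos (6.23 ± 0.23, 1701 ± 183 against 22.7 ± 3.40 CPM) and Egr1 (11.60 ± 0.40). Socs3, Dusp1, Zfp36, Egr2 and Nr4a1 stand on this list and also on the anti-inflammatory, transcription factor or monocyte lists. Fibroblast markers had 19 of 20 higher (19 higher and 1 lower over the list alone, adjusted p = 1.10e-08, adjusted p = 0.0998 with an estimated correlation), with Col1a1 at 43.7 ± 14.5 against 1.22 ± 0.228 CPM. Xist, which is expressed from the inactive X chromosome of females, had 151 ± 50.4 against 0.0597 ± 0.0654 CPM (log2 fold change 11.02; 1 BMDM count and 6740-fold, 1210 to 266000, without BMDM G). Sorted cells and culture also differed in strain and tissue and, by Xist, in the sex of the mice, which cannot be told apart from the cell type here. In total 2911 genes were higher and 2579 lower, of which 2310 and 2014 kept their call with every library thinned to the smallest total, a setting chosen after the data were seen. Of all called genes 2086 and 1558 differed at least 2-fold, with 6435 at an unadjusted p under 0.05 and no overlap for 63.1% of genes, against 10% by chance.

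The third comparison set interstitial macrophages against BMDM. Aqp1, a water channel gene (ENSMUSG00000004655, chromosome 6, 55336432 to 55348555, plus strand), had 3637 ± 352 against 0.520 ± 0.124 CPM (log2 fold change 12.74 ± 0.32 SE, n = 3 per group, edgeR adjusted p = 3.06e-10). Lyve1 was higher by 14.96 ± 0.45 (3303 ± 598 against 0.0885 ± 0.113 CPM; 1 BMDM count and 133000-fold, counting interval 23800 to 5250000, without BMDM G). Chp2, a calcineurin-like calcium-binding protein gene (ENSMUSG00000030865, chromosome 7, 122219496 to 122222824, plus strand), had 2744 counts in interstitial and 0 in BMDM, at least 3240-fold higher, or at least 2080-fold without BMDM G. Cd209f was at least 2560-fold higher, or at least 1650-fold without BMDM G. Retnla, a secreted protein induced by interleukin 4, had 13190 against 1 counts and 919.6 ± 969.7 against 0.0153 ± 0.0266 CPM, a ratio of 46800-fold with a counting interval of 8390 to 1850000. Without interstitial F the ratio was 17500-fold (3140 to 691000), and the call was lost without BMDM I (adjusted p = 0.0768). Tmem171 (ENSMUSG00000052485, chromosome 13, 98686235 to 98694834, minus strand) had 0 counts in interstitial and was at least 175-fold lower, or at least 68.3-fold without interstitial E. Slco4a1 was lower (log2 fold change -8.99 ± 0.46), as was Spp1 (-8.71 ± 0.64, and -9.62 without interstitial F). Cx3cr1, whose reporter was negative in this sort, was lower (-5.76 ± 0.28, 4.92 ± 2.66 against 278 ± 38.1 CPM).

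Both comparisons with BMDM share the BMDM libraries, so lists called in each are not independent findings. Of 25 resident tissue macrophage genes 20 were higher and 1 lower, the same over the list alone (adjusted p = 5.07e-23, adjusted p = 0.0944 with an estimated correlation), with Cd163 at 9.43 ± 0.33 and Pf4, a platelet-type chemokine gene, at 6.77 ± 0.35. Alternative activation genes were higher for 16 of 19, the same over the list alone (2.29e-10 and 0.0944, the second with an estimated correlation, as in the pairs that follow), including Mrc1 (5.22 ± 0.29, 3855 ± 1168 against 103 ± 31.7 CPM) and Il13ra1 (3.97 ± 0.22). All 30 cell cycle genes were lower, over all genes and over the list alone (5.26e-24 and 0.0730). Also lower were 17 of 25 interferon genes, 17 over the list alone (8.82e-07 and 0.227), and 19 of 22 cholesterol synthesis genes, 20 over the list alone (1.74e-05 and 0.0944). TREM2 and lipid-handling genes were called lower as a list, with 14 lower and 3 higher of 24 (4 and 14 higher and lower over the list alone, 0.00637 and 0.154), including Ctsd (-3.05 ± 0.19, 471 ± 84.0 against 3887 ± 212 CPM) and Lipa (-2.20 ± 0.15) lower and Abca1 (4.88 ± 0.23) higher. Complement genes had 11 higher and 2 lower of 18 (12 and 2 over the list alone, 1.82e-05 and 0.0944). Uptake genes had 9 and 6 of 20, the same over the list alone (0.00412 and 0.101, and the call of apoptotic cell uptake receptors and bridging molecules was lost at 0.105 with no filter). Class II presentation had 13 of 16 higher, the same over the list alone (1.62e-05 and 0.153), with Cd86 at 4.67 ± 0.25. These 4 lists were written with knowledge of the study.

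Macrophage transcription factors had 18 higher and 6 lower of 30 (19 and 6 over the list alone, adjusted p = 5.92e-04, adjusted p = 0.141 with an estimated correlation, in that order for the lists that follow), with Klf4 at 4.83 ± 0.15 and Irf7 at -2.67 ± 0.30. Inflammatory cytokines and chemokines had 13 and 2 of 22 (14 and 2 over the list alone, 0.00412, 0.272), with Ccl6 at 4.72 ± 0.19. Anti-inflammatory mediators had 10 and 1 of 18, the same over the list alone (6.73e-07, 0.0640). Growth factors and their receptors had 12 and 2 of 22 (13 and 2 over the list alone, 5.92e-04, 0.0944), with Ednrb at 7.98 ± 0.54 (441 ± 202 against 1.72 ± 0.494 CPM). Pattern recognition receptors had 12 and 4 of 23, the same over the list alone (0.0107, 0.346, and the call of pattern recognition receptors was lost at 0.102 with the term for the matched libraries), with Clec4a1 at 4.89 ± 0.28. That term sets the comparison at the level of interstitial D. Lists without a call were lysosome genes, with 7 higher and 10 lower of 26 (7 and 13 over the list alone, adjusted p = 0.282), adherens junction genes, 4 and 2 of 12 (6 and 3, 0.215), and glycolysis genes, 1 and 4 of 20 (1 and 3, 0.0959). With the same counts over the list alone these were sort and identity genes, 3 and 2 of 10 (0.549), tight junction genes, 7 and 2 of 12 (0.650), polarity genes, 8 and 3 of 18 (0.558), and monocyte genes, 6 and 2 of 18 (0.282). In lining against BMDM the sort and identity list was called higher with 6 of 10 and 7 over the list alone (0.0260 and 0.265), a call lost without lining A (adjusted p = 0.0607). It holds Cx3cr1, by whose reporter the lining cells were sorted.

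Here too the sorted cells differed from culture in handling and other-cell markers. Immediate early and heat shock genes had 20 higher and 1 lower of 24, the same over the list alone (adjusted p = 7.04e-25, adjusted p = 0.105 with an estimated correlation), with Fos at 1687 ± 401 against 22.7 ± 3.40 CPM. Fibroblast markers had 17 of 20 higher (19 over the list alone, 1.68e-09 and 0.120), with Col1a1 at 41.4 ± 13.9 against 1.22 ± 0.228 CPM. Dendritic cell markers had 8 higher and 1 lower of 10 (9 and 1 over the list alone, 0.0246 and 0.200, and 0.171 with the term for the matched libraries, which ends the call of dendritic cell markers), with Zbtb46 at 19.4 ± 2.44 against 0.603 ± 0.0795 CPM. That term sets the comparison at the level of interstitial D. Xist had 156 ± 139 against 0.0597 ± 0.0654 CPM (log2 fold change 11.09, and 10.44 without interstitial E; 1 BMDM count and 8860-fold, 1590 to 350000, without BMDM G). In total 2954 genes were higher and 2688 lower, of which 2333 and 2055 kept their call with the thinned libraries. Of all called genes 2180 and 1630 differed at least 2-fold, with 6574 at an unadjusted p under 0.05 and no overlap for 62.2% of genes, against 10% by chance. Strain, tissue and handling differed together with the cell type in this comparison as well. Sex, as read from Xist, did so in part, with Xist above the floor in interstitial E and F, at 0 in interstitial D and not above the floor in BMDM.

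**Figure D3:**
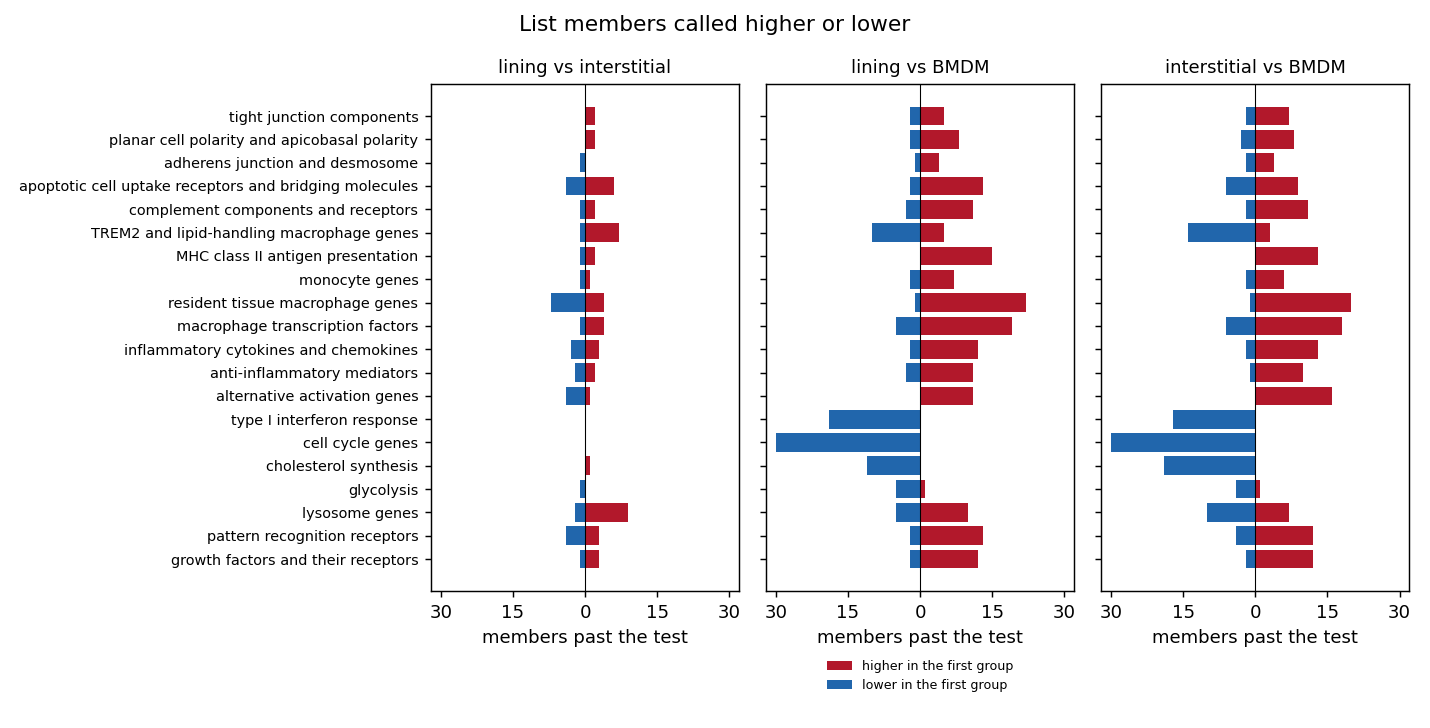
Number of members of each of the 20 biology lists called higher (red, to the right) or lower (blue, to the left) in the first group of each comparison at an adjusted p under 0.05. All 30 cell cycle genes lie on the lower side in both comparisons with BMDM, and none was called between lining and interstitial.

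Genes that set a group apart from both others numbered 289 for lining, 198 for interstitial and 1970 for BMDM. Those named by the fixed rule for lining were Myh15, Chst1, Tspan18, Ecscr, Ifitm10 and Dusp27. Ecscr, an endothelial cell surface regulator gene, had 101 ± 54.1 against 1.90 ± 1.28 CPM in lining against interstitial (log2 fold change 5.69, and 6.37 without interstitial E), and Ifitm10 had 15.7 ± 2.74 against 0.242 ± 0.420 CPM (5.38, and at least 37.8-fold without interstitial E). Tspan18 (5.94 against interstitial) lost its call without lining A (5.15), lining B or interstitial E (4.82), with a highest adjusted p of 0.0938, and was at least 87.3-fold higher without interstitial D. Dusp27 (5.29) lost its call without lining A or C (highest adjusted p = 0.0719) and was at least 18.4-fold higher without interstitial E. For interstitial the named genes were Lbx1, Ccl8, Barx2, Cd209f, Cd209g and Cd209b, and for BMDM Slco4a1, Npy, Nkain1, Tox2, Hmga2 and Ifi44. Npy, the neuropeptide Y gene, had 5760 counts in BMDM, 1 in lining and 4 in interstitial (log2 fold change -8.50 in interstitial against BMDM, -7.28 without interstitial E, and at least 398-fold lower without interstitial F). Hmga2, a chromatin protein gene, had 7481 in BMDM and 5 in interstitial (-8.56, and -7.33 without interstitial E; 1 interstitial count and 1550-fold lower, counting interval 278 to 61300, without interstitial F). Without lining A these gene numbers for lining and interstitial were 169 and 94, and without lining B 173 and 125. The interstitial number was 115 without interstitial E and 110, 116 and 119 without BMDM G, H and I.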

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

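The test of the difference between lining and interstitial was planned, and the genes named below besides Cx3cr1, Itgb5, Fat3, Trem2, Ccl4 and Ccl9 were chosen after their values were seen. Against BMDM, 25 genes were called in opposite directions in the lining and interstitial macrophages, and for each of the 25 the difference between the sorted groups was called, which nearly follows from choosing genes with opposite calls. Another 2304 genes called higher and 1970 lower than BMDM in both sorted groups. Itgb5, the integrin beta 5 chain, was 1.63 higher in lining than in BMDM on the log2 scale and -1.99 in interstitial against BMDM, with 3.63 ± 0.18 between the sorted groups (adjusted p = 1.04e-06). Trem2, a lipid-sensing receptor gene, had 0.62 and -1.01 (difference 1.63 ± 0.15, adjusted p = 7.08e-05) and Ccl4, a chemokine gene, 0.69 and -1.25 (difference 1.94 ± 0.21, adjusted p = 1.71e-04). Ass1, an enzyme of arginine synthesis, had 1.31 and -2.17 (difference 3.48 ± 0.34). In the other direction Slc40a1, the iron exporter ferroportin, had -1.23 in lining and 1.41 in interstitial (difference -2.63 ± 0.36), as did the chemokine gene Ccl9 with -0.50 and 0.93. Fat3 had 2.62 in lining against BMDM and 2 against 212 counts in interstitial against BMDM, 29.9-fold lower with a counting interval of 8.17 to 248 (fitted -4.65; 11.7-fold, 3.19 to 97.1, without interstitial E and at least 14.7-fold without interstitial F). The 2 differences against BMDM share the BMDM libraries, which correlates them. Across genes the correlation of the log2 differences was 0.850, against a mean of 0.426 in 20 simulations with no effect, and independent lists of these sizes would share 682 higher and 549.8 lower genes.

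After Fat3, Cx3cr1 had the largest difference among the 25, with 7.11 between lining and interstitial, 1.35 in lining against BMDM and -5.76 in interstitial against BMDM. The difference itself was tested (adjusted p = 1.46e-07, higher in 3 of 3 lining libraries than in any interstitial library). The GFP reporter of the sort stands in this gene, so the value follows from how the cells were sorted. No technical explanation was tested for these genes, and the position of the cells in the tissue is the biological difference the design names.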

How the results depend on the processing

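Thinning the libraries, the surrogate variable, the term for matched libraries and the fits without lining C and interstitial F were chosen after the data were seen, and the other alternatives before. A pairing from the labels could not be analysed, because they give none and the sorted samples share no letter. The matched libraries were matched on the data. Of 157 genes named between lining and interstitial, 80 were called, and 30 of these kept their call in all 24 settings. Other named genes gained a call, 22 by DESeq2 with 0 lost and 17 with the term for matched libraries with 3 lost. Among these Adgre1 passed in both and Tjp1 with the term. Since the term was matched on these same data, a call gained with it is no added support. Of 156 named in lining against BMDM 147 were called and 116 kept, and of 156 in interstitial against BMDM 143 were called and 113 kept.

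With an estimated correlation between genes, 0 lists were called between lining and interstitial, 3 in lining against BMDM and 0 in interstitial against BMDM, in place of 9, 16 and 17. With fry they numbered 10, 28 and 27. DESeq2 called 591 genes lower in lining than interstitial and 406 for interstitial against both other groups. At an adjusted p under 0.01, lining against interstitial kept 215 higher and 75 lower, lining against BMDM 1635 lower, and the genes of 1 group against both others numbered 140, 61 and 1266 for lining, interstitial and BMDM. Testing against a 2-fold difference left 78 and 31, 1356 and 799, and 1454 and 881 higher and lower genes in the 3 comparisons and 49, 26 and 614 against both others. These limits are stricter by construction. With only the 6 sorted libraries lining against interstitial had 255 and 111. Fits of only the 6 samples compared gave 3132 and 3451 in lining against BMDM. In interstitial against BMDM they gave 3120 and 2919, also from fewer samples. The fit of all 9 samples shares its spread with BMDM, whose libraries correlated at 0.996 to 0.997, above those of either sorted group. The cause of the fall was not tested.

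With 1 surrogate variable 469 genes were lower in lining than interstitial and 327 marked interstitial. With a term for the matched libraries there were 744 higher, 539 lower and 315 for interstitial, and without lining C and interstitial F 445 lower and 337 for interstitial. The term and the surrogate variable were drawn from these same data and take shared deviations out of the spread. Higher numbers with either are therefore no added support. The cause was not tested further for these settings or for DESeq2. With the term for the matched libraries 2 of the 156 named genes reversed in lining against BMDM. That fit sets both comparisons with BMDM at the level of lining A and interstitial D, so it compares a different quantity. The same holds for its number of genes for interstitial against both others. Whether this accounts for the reversals was not tested. S100b in interstitial against BMDM ranged from -1.23 without interstitial E, its only interstitial library with counts, to 6.62 without BMDM I.

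Leaving out 1 library at a time gave 276 (without lining A) to 517 (without interstitial F) genes higher in lining than interstitial and 120 (without lining A) to 371 (without interstitial F) lower. In lining against BMDM the ranges were 2061 to 3174 and 1852 to 3231, and in interstitial against BMDM 2152 to 3247 and 1992 to 3024. For genes of 1 group against both others they were 169 (without lining A) to 300 (without lining C), 94 (without lining A) to 271 (without interstitial F) and 1433 to 2299. With the term for matched libraries, comparisons with BMDM are set at the level of lining A and interstitial D. With it the call of pattern recognition receptors was lost in lining and in interstitial against BMDM (adjusted p = 0.0750 and 0.102). In interstitial against BMDM, that of apoptotic cell uptake receptors and bridging molecules was lost with no filter (0.105), and that of dendritic cell markers with the filter on mean CPM (0.05005), with the term (0.171) and without lining C and interstitial F (0.0524). Lists called ranged from 7 to 12, 15 to 18 and 17 to 20. DESeq2 scaling factors, library size only, no filter, a filter on mean CPM, limma-voom, the fit without robust estimation, the fit without other-cell genes and thinning moved no count of genes by more than 1.5 times. The genes behind a count changed more. Of the 473 higher and 259 lower genes between lining and interstitial, limma-voom also called 354 and 175, no filter 413 and 210 and thinning 379 and 203.

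With library size only the median log2 difference of all tested genes was -0.11 in lining against BMDM. With no filter, which adds genes near 0, it was -0.17 and -0.19 in lining and interstitial against BMDM, and with the DESeq2 test and its own set of genes 0.32 and 0.27. Depth limits the sorted libraries most, where 3 counts correspond to 0.269 to 1.37 CPM.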

Other observations

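The gene families and matrix genes of this part, the tests of RNA from fibroblasts and from pericytes, of dissociation, of a shared preparation and of one pool of mice were chosen after the result was seen, and the tests by library size and by splits before. The adjusted p of a family is from camera, adjusted over the chosen families only. Since the families were chosen on these same data, it gives no independent support. C-type lectin genes are named for sugar binding, which not every member shows. They parted the sorted groups, with 1 higher and 13 lower of 23 in lining against interstitial (family median -1.33, camera adjusted p = 6.04e-08, adjusted p = 0.384 with an estimated correlation). The dendritic cell and endothelial lists were also called lower (medians -1.86 and -1.73, adjusted p = 0.00245 and 8.45e-04, and 0.111 for each with an estimated correlation), with 1 of 10 and 1 of 11 markers called, though the sort took cells with CD45, CD11b and F4/80, and Cd209a stands on the dendritic list. The most abundant in interstitial were Cd209a at 66.2 CPM, Siglech at 51.9 and Vwf at 47.2. Besides those in the report the lower members included Clec2d (-1.39 ± 0.27, adjusted p = 0.0110) and Clec3b, which encodes tetranectin (-4.20 ± 1.03, adjusted p = 0.0344). Arg1, an arginine-degrading enzyme used as a mark of alternative activation, was listed at 0 in lining A and interstitial D, at 2.86 and 0.0909 CPM in lining B and interstitial E, and at 1247 and 2321 CPM in lining C and interstitial F. Its difference between the groups did not pass (log2 fold change -0.90 ± 2.95, adjusted p = 0.910).

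Against BMDM several families moved together in both sorted groups. The medians kept their sign under each scaling alternative, which says little, since scaling moves all genes alike. With library size only the median of all tested genes was -0.11 in lining against BMDM. The smallest family median in size was -0.28, for cytosolic ribosomal proteins in interstitial. Kruppel-like factors, transcription factors linked to quiescence, were higher for 10 of 13 in lining and 11 of 13 in interstitial (medians 1.75 and 2.30, adjusted p = 3.04e-07 and 2.01e-08, and 0.00902 and 0.00590 with an estimated correlation). Klf2 differed by 2.92 ± 0.22 and 2.83 ± 0.22 and Klf9 by 3.96 ± 0.38 and 4.30 ± 0.39. Clock genes were higher for 14 and lower for 2 of 17 in lining, and 14 and 1 in interstitial (medians 2.48 and 2.24, adjusted p = 7.67e-06 and 1.19e-05, and 0.0232 and 0.0306 with an estimated correlation), with Per1 at 2.67 ± 0.25 and 3.11 ± 0.25 and Clock at 1.02 ± 0.23 and 1.10 ± 0.23. Proteasome subunits were lower for 21 and 26 of 39 (adjusted p = 0.000626 and 0.000163, and 0.259 and 0.192 with an estimated correlation) and the chaperonin CCT subunits for 7 and 7 of 7 (0.000417 and 0.00378, and 0.185 and 0.192), such as Cct7 at -1.27 ± 0.14 and -1.13 ± 0.14. Cytosolic ribosomal protein genes were lower for 45 and 26 and higher for 1 and 1 of 77 (adjusted p = 0.000147 and 0.00637, and 0.436 and 0.582 with an estimated correlation). Mitochondrial ones were lower for 29 and 35 of 77, with 1 higher in lining (0.000262 and 2.85e-05, and 0.120 and 0.0759). The sorted cells and the culture differ in handling, strain, tissue and sex-linked transcripts as well as cell type, so no source of these differences is offered.

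Some genes of the extracellular matrix, 8 chosen because they were higher in lining than in interstitial, are described here, and others were not higher, such as Dcn (32.9 against 59.7 CPM), Prg4 (52.4 against 188) and Postn (4.11 against 23.3). Sparc was 25.1-fold higher (4.65 ± 0.26, 2419 ± 717 against 95.8 ± 22.4 CPM), Mmp2, a gelatinase, differed by 4.35 ± 0.37, Htra3, a serine protease, by 3.96 ± 0.35, and the membrane protease Mmp14 by 2.96 ± 0.61. With Vcan, Adamtsl2, Npnt and Cspg4 the 8 genes had a median of 4.33. RNA from fibroblasts carried into the lining sort would raise fibroblast markers by about as much, and their median over 20 tested markers was -0.51 (SD 1.45), with Col1a1 at 43.7 ± 14.5 against 41.4 ± 13.9 CPM and Col1a2 at 43.3 ± 7.40 against 56.0 ± 13.3 CPM. Pericyte and smooth muscle markers without Cspg4 had a median of -0.71 (SD 1.63). Both lie under the matrix genes by more than 2 SD. That distance is set in part by the choice, since the 8 genes were picked for being higher and include Cspg4. Apart from that choice, neither marker list was higher in lining by its median (-0.42 for the pericyte list with Cspg4). This argues against either cell type as the whole source. Of the 20 fibroblast markers 19 and 17 were higher in lining and in interstitial than in BMDM, although the sort was on CD45, CD11b and F4/80, and no test parted fibroblast RNA from expression by macrophages there. Expression by the lining macrophages themselves may explain the levels and was not tested further.

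The immediate early and heat shock genes that were higher in both sorted groups than in BMDM had medians of 4.18 in lining and 3.79 in interstitial. With every library thinned to the smallest total the smaller ratio of the thinned to the full median was 0.983. Thinning keeps the expected fold of a well-counted gene, so this ratio was nearly set in advance and cannot decide on library size. Other properties that go with depth were not tested. Dissociation and sorting touched every sorted library and no BMDM library. Between lining and interstitial edgeR called 0 of its 24 members, with 2 higher and 2 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. Handling and tissue therefore cannot be told apart as a source of this difference.

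Within their groups, lining A deviated from its group mean like interstitial D (correlation over 4495 genes, which are not independent, 0.407), lining C like interstitial F (0.364) and lining B like interstitial E (0.177). This matching was the 1 of 6 one-to-one matchings with the highest summed correlation, 0.948 against 0.432 for the next. A preparation shared by a lining and an interstitial library could explain it but cannot be told apart from chance with 6 matchings, whose share is never under 0.167. Thinned to the smallest total, the smaller of the correlations for A with D and C with F was 0.278, which argues against the total of counts alone. The matching does follow depth, with A and D the smallest and B and E the largest libraries of their groups. Thinning equalises totals only, so other properties that go with depth were not tested. One pool of mice for lining A and interstitial D is excluded by Xist, with 198 counts in lining A and 0 in interstitial D, a CPM 72.2 times the floor. Flt1, a growth factor receptor of endothelium, was at 306 CPM in lining C and 407 in interstitial F and at or under 14.5 in each other library. No biological explanation was tested, since the labels name none.

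Sex-linked genes were mixed in the sorted libraries, with Xist above the floor in 5 of 6. Summed Y-linked genes had 106, 79.8 and 112 CPM in lining, 162, 85.6 and 53.0 in interstitial and 185, 153 and 170 in BMDM, where Xist was at 0.130, 0.0496 and 0 CPM. As far as these genes show, sex differed between BMDM and the sorted libraries other than interstitial D. It cannot be told apart from cell type in the comparisons with BMDM.

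Higher and lower gene numbers were compared with those of other splits of the 6 libraries. With 10 splits the share is never under 0.1, so the splits are too few for a share under 0.05. Lining against interstitial gave 473 higher and 259 lower, against at most 1 and 1 in another split, and each was the 1 split of 10 with as many. Lining against BMDM gave 2911 and 2579 and interstitial against BMDM 2954 and 2688, against 0 and 0 by edgeR in any other split. Each other split mixed BMDM with sorted libraries, which adds spread, so these 0 counts say little. For the number of lists called, 4, 6 and 4 of 10 splits had as many as the real 9, 16 and 17, and the highest others were 14, 19 and 19. The splits with 14 set lining A, lining B and interstitial D against the rest, and lining A, lining C and interstitial D against the rest, so lining A and interstitial D stood together in each. Of 100 partitions of the 9 libraries into 3 groups, the real one alone gave as many genes against both others, 1 of 100 for lining (289, highest other 14), interstitial (198, highest other 0) and BMDM (1970, highest other 1795). These partitions say little about the groups, since 97 of the 99 others mixed BMDM with sorted libraries, which adds spread. Only 10 partitions keep the BMDM libraries together, too few for a share under 0.05, and the highest numbers in the 9 others were 0 for lining, 0 for interstitial and 1853 for BMDM.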
